A study of Mus musculus with 8 samples.

How the data were processed

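RNA levels were measured on Affymetrix mouse arrays in macrophages from the peritoneal cavity. Per the labels' protocols, mice received 3% thioglycolate into the peritoneum, cells were collected 4 days later and kept by adherence, and the cultures then stood for 24 h without or with 1 µM corticosterone. The cells came from mice whose mineralocorticoid receptor gene, Nr3c2, is deleted in myeloid cells (knockout) or floxed but intact (control), all labelled male C57BL6/J. This gives 4 groups of 2 arrays, 8 arrays in all. Per the labels, each sample was pooled from experiments in triplicate, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision. The Cre driver, the date of each hybridisation and the handling of arrays that stand apart are not given in the sources used here.

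The deposited values are log2 expression levels, 1 per probe set and array. Per the submitters' processing notes they were made with RMA in R 2.7. RMA subtracts background, makes the distributions of the arrays alike and summarises the probes of a set, so values are relative within an array, a change in total RNA per cell leaves no trace, and values near the background are compressed towards it. Array medians lay between 5.55 and 5.58. The value of a probe set gives no detection call, so signal over background was not tested per gene.

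Of 45101 probe sets, 64 were controls, 34958 had 1 gene in the platform annotation, 932 had several and 9211 were not named here. For 34754 of the probe sets with 1 gene the symbol was matched through its identifier to the gene table of assembly GRCm38.p6, and 204 kept the older symbol. Each gene was represented by its probe set with the highest mean over the 8 arrays, which left 18193 genes; 9010 of them had more than 1 probe set. Every column of values belonged to a labelled sample.

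The model was fitted with limma 3.58.1 in R 4.3.3, with 1 coefficient per group, variances shared over the 4 groups and moderated with a trend on the mean level. From it came 7 contrasts: knockout against control without and with corticosterone, corticosterone against none in control and in knockout cells, the interaction of both, and the average effect of each factor. Adjusted p-values are limma's, by the method of Benjamini and Hochberg over all genes, called under 0.05 with no minimum fold. Errors given as SE come from this fit. Fold changes are log2 differences.

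The groups, the contrasts, the tests, the gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. After the values were seen, the fit without control untreated replicate 2, planned as 1 of the fits that leave out an array, was taken as a second result beside the fit of all arrays, because that array stood far from the other 7. The 2 fits are called 8 arrays and 7 arrays. With 7 arrays the control untreated group is a single array, whose spread is assumed to be like that of the other groups. Residual degrees of freedom were 4 with 8 arrays and 3 with 7, and the median SE of a contrast of 2 arrays against 2 was 0.2 log2 units with 8 arrays and 0.105 with 7. A fit of 5 arrays, also chosen after seeing the data, further left out knockout untreated replicate 2 and knockout corticosterone replicate 1. Both read somewhat higher than their replicates for the 1601 genes that lay over 2 log2 units above replicate 1 on control untreated replicate 2: replicate 2 minus 1 had a median of 0.26 in knockout untreated cells (78.5% positive) and -0.18 in knockout corticosterone cells (25.1% positive), against -0.0096 in control corticosterone cells (47.7% positive).

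The genes named are, per contrast, the 10 with the largest increase and the 10 with the largest decrease among those called whose replicates did not overlap. Where fewer than 5 were called, they are the 10 with the smallest p, said not to pass. Nr3c2, the glucocorticoid receptor gene Nr3c1, the prereceptor enzymes Hsd11b1 and Hsd11b2, and Lyz1 and Lyz2, at whose locus the Cre most used for myeloid cells lies, are always included, as are up to 4 members with the smallest p from each list. Genes outside this rule were chosen after their values were seen and are named as such.

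There were 26 gene lists, 17 of pathways and 9 of cell types. Each was tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with the correlation estimated from the data and with fry. With 7 arrays no list passed with an estimated correlation in any of the 7 contrasts. With 8 arrays 4 lists passed in the corticosterone contrast of knockout cells and 1 in the average corticosterone effect.

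The fit was tested on simulated data of 18193 genes with 200 changed. Noise was drawn independently for each gene, so the list test below cannot show which correlation between genes suits real lists. A gene's noise had the same spread on every array. In the data replicates differed by a median of 0.47 log2 units in the control untreated group, against 0.072 to 0.096 in the others. The values below for 8 arrays therefore describe arrays of equal spread, which these are not. Unchanged genes were called too: 25 beside 178 changed ones for the average genotype effect at 1.5-fold with 7 arrays. For the interaction at 4-fold with 8 arrays they were 11 beside 99, both above the share of 0.05 that the threshold implies. At 2-fold the average genotype effect with 8 arrays had 2 beside 87, under that share. For the average genotype effect 8 arrays recovered 84% of 4-fold, 43.5% of 2-fold and 0% of 1.5-fold changes, and 7 arrays 100%, 100% and 89%. For the interaction the shares were 49.5%, 0% and 0% with 8 arrays and 99.5%, 77% and 49% with 7. A shifted list was found by camera at the preset correlation (adjusted p = 8.76e-08 with 8 arrays and 7.33e-08 with 7) and missed with an estimated one (adjusted p = 0.0715 and 0.183).

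Alternatives were no variance trend, a robust prior, a filter on the dimmest 40% of genes, the mean of a gene's probe sets, every probe set, a further quantile normalisation, median centring, array weights, the replicate number as a block, a minimum of 1.5-fold, only the arrays compared, and each array left out. Correlations of fold changes are across genes, which are not independent replicates. Their chance values come from 100 draws of arrays with no effect and the same spread on every array.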

Results

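Macrophages recruited to the peritoneal cavity by thioglycolate were profiled from control mice and from mice with a myeloid deletion of the mineralocorticoid receptor, a nuclear receptor that binds aldosterone and corticosterone. Cells of each genotype were kept without hormone or with corticosterone, the main glucocorticoid of mice, which gave 4 groups of 2 arrays. The comparisons ask which transcripts differ with the receptor, which respond to the hormone, and whether the response differs between genotypes. The macrophage transcripts Lyz2 and Csf1r were near the top of the scale on all 8 arrays. Lyz2, a lysozyme, lay between 13.58 and 13.78 log2 units. Csf1r, the receptor for macrophage colony stimulating factor, lay between 13.52 and 13.59 (Csf1r was chosen after its values were seen). The macrophage identity list averaged 11.26 on control untreated replicate 2 and between 11.56 and 11.81 elsewhere.

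Control untreated replicate 2 stood apart from the rest. Its median correlation with the other arrays was 0.919, against 0.994 to 0.995 for the others. The difference between the 3′ and 5′ control probe sets, which grows as RNA breaks, was 2.18 log2 units for Actb against 0.41 to 0.62 on the other 7 arrays, and 1.84 for Gapdh against 0.65 to 0.79. Replicates differed by a median of 0.47 log2 units in the control untreated group, 0.072 in the control corticosterone group, 0.096 in the knockout untreated group and 0.077 in the knockout corticosterone group. The number of genes whose replicates differed by over 1 log2 unit was 4630, 3, 76 and 21 in the same order. Among genes chosen after their values were seen, collagen transcripts were far higher on this array, with Col3a1 at 13.04 against 9.60 to 10.28 on the others and Col1a2 at 12.53 against 8.81 to 9.69. The list of mesothelial and fibroblast markers averaged 8.95 there and between 7.02 and 7.52 elsewhere, and the cell cycle list averaged 9.37 there and between 7.40 and 8.41 elsewhere. Results are therefore given from 8 and from 7 arrays. Leaving this array out does not remove signal that other arrays may share with it. Without hormone the cell cycle list averaged 8.34 and 8.41 in knockout cells and 7.95 on control untreated replicate 1. With hormone it averaged 7.92 and 7.77 in knockout cells and 7.42 and 7.40 in control cells. Whether signal like that of control untreated replicate 2 adds to this genotype difference was not tested.

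**Figure D1:**
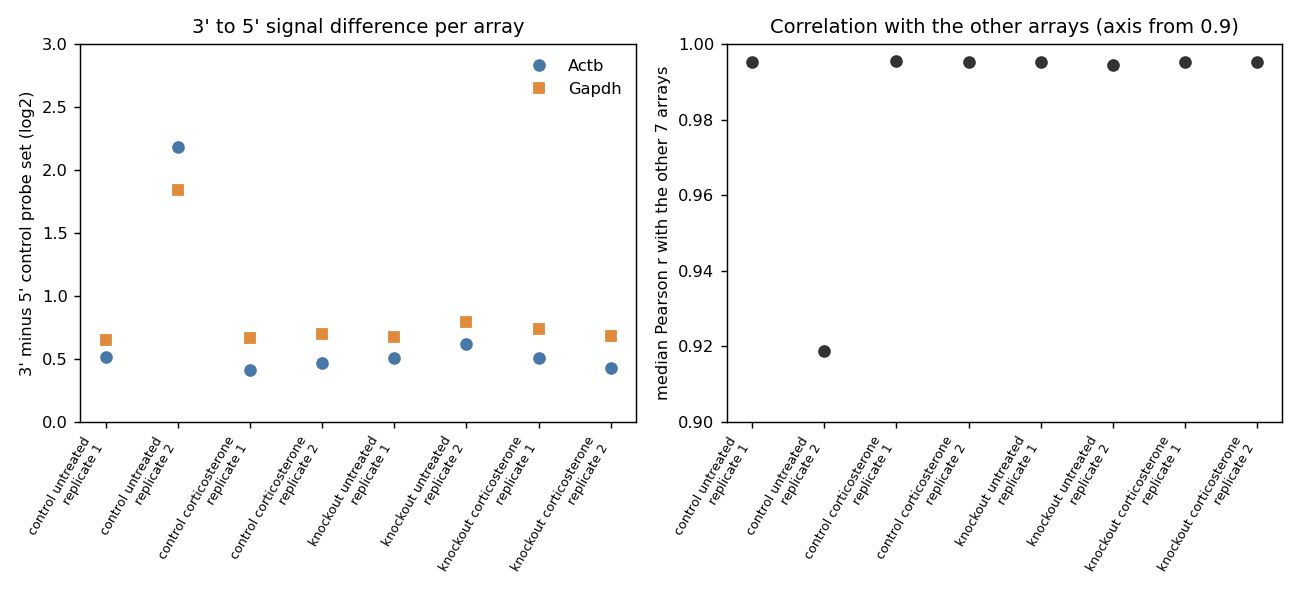
Quality of the 8 arrays: the 3′ minus 5′ difference of the Actb and Gapdh control probe sets (log2 units) and the median correlation of each array with the others. Control untreated replicate 2 lies at 2.18 for Actb and at a correlation of 0.919, away from the other 7 arrays.

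The deleted gene itself was low. Nr3c2 was read by 1 probe set, at 6.39 and 8.46 on the control untreated arrays, 6.39 and 6.13 on the control corticosterone arrays, 5.54 and 5.82 on the knockout untreated arrays and 5.11 and 5.47 on the knockout corticosterone arrays, so that each knockout array lay below each control array. With 7 arrays Nr3c2 fell by 0.97 log2 units (SE 0.18, limma adjusted p = 0.0290) in knockout cells with corticosterone. The call was lost without control corticosterone replicate 1 (adjusted p = 0.335), its replicate 2 (adjusted p = 0.157) or knockout corticosterone replicate 1 (adjusted p = 0.232), and without the variance trend (adjusted p = 0.182) or with 5 arrays (adjusted p = 0.118). Without the hormone the difference was -0.71 (SE 0.21, adjusted p = 0.161) and did not pass. With 8 arrays neither difference passed, at -0.97 (SE 0.65, adjusted p = 1) with and -1.75 (SE 0.65, adjusted p = 0.486) without the hormone; the first passed with array weights (adjusted p = 0.0210) and from only the arrays compared (adjusted p = 0.0108). Where the probe set lies relative to the deleted part is not given in the sources used here; a probe set outside that part would check nothing about the labels. Nr3c1, the glucocorticoid receptor gene, lay between 10.54 and 11.32. With 7 arrays Nr3c1 fell by 0.19 (SE 0.04, adjusted p = 0.0149) with corticosterone in knockout cells, a call lost without knockout corticosterone replicate 1 or 2 (adjusted p = 0.110 and 0.0564), without the variance trend (adjusted p = 0.142) and with the mean of its probe sets (-0.12, adjusted p = 0.294). With 8 arrays this fall passed with array weights (adjusted p = 0.0395) and from only the arrays compared (adjusted p = 0.0392). In control cells with 7 arrays Nr3c1 changed by -0.14 and did not pass, except with the mean of its probe sets (-0.30). The interaction was -0.055, so the fall was not shown to differ between genotypes. Its difference between genotypes did not pass with 7 arrays, at 0.04 without and -0.01 with the hormone. Without control untreated replicate 1, which leaves the array that stands apart as the whole group, the genotype difference without hormone was -2.79 for Nr3c2 and 0.73 for Nr3c1 (adjusted p = 2.4e-06 and 1.76e-06). Hsd11b1, which regenerates active glucocorticoid, lay at 6.71 or below, and Hsd11b2, which inactivates it, between 3.49 and 4.39. Neither they nor Lyz1 and Lyz2 were called in any contrast.

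In control cells the largest increases with corticosterone on 8 arrays, among called genes whose replicates did not overlap, were those of Cd163, Orm2, Fkbp5 and Chil3. Cd163, the receptor for haemoglobin bound to haptoglobin, rose by 4.38 log2 units (SE 0.20, adjusted p = 0.00939, n = 2 per group). Orm2, an acute phase glycoprotein, rose by 3.89 (SE 0.26), Fkbp5, a co-chaperone that restrains steroid receptors, by 3.55 (SE 0.21) and Chil3, a chitinase-like protein of alternatively activated macrophages, by 3.29 (SE 0.16). Cbr2 rose by 2.75, Nipal1 by 3.15, Ms4a6c by 2.50, the metallothionein Mt2 by 2.17, Rnase4 by 1.89 and Mertk, a receptor for apoptotic cells, by 1.81. The natural killer receptor gene Klrb1a fell by 2.69 (SE 0.22), Acap1 fell by 2.09, Siglecf fell by 1.17, the prostacyclin synthase gene Ptgis fell by 1.00 and the fibronectin gene Fn1 fell by 0.90. Ryr1 fell by 1.85 on its brightest probe set, while another of its probe sets gave 0.01; the 2 other probe sets of Fkbp5 gave 0.0069 and 3.81. In all, 31 genes were called by limma, 25 higher and 6 lower, and 1556 had an unadjusted p under 0.05. Of 26 gene lists 11 passed camera, none with an estimated correlation; for the glucocorticoid-induced genes, with 6 of 38 higher and 9 adjusted over the list alone, adjusted p = 1.78e-07, and adjusted p = 0.0692 with an estimated correlation. The count was 0 without either control corticosterone array, without either knockout corticosterone array or with only the arrays compared, 1 without either knockout untreated array, 11678 without control untreated replicate 1, and 1964 without replicate 2. It was 7 with array weights.

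Those 1964 genes of the 7 arrays were 882 higher and 1082 lower, and they held all 31 called with 8. Lyve1, a hyaluronan receptor, rose by 3.83 log2 units, Ms4a6b by 3.35, Cdo1, a cysteine dioxygenase, by 3.19, the sulfotransferase gene Sult1a1 by 3.16 and Slc24a3 by 2.91. Ipcef1 fell by 2.71, Psrc1 fell by 2.55, Cd209a fell by 2.27, Pald1 fell by 2.16, Acod1, which makes itaconate, fell by 1.99, Fgr fell by 1.88 and Gimap8 fell by 1.83. Other probe sets gave -0.70 to 0.01 for Ipcef1 and -2.02 to -0.23 for Psrc1. Of 38 genes known to be induced by glucocorticoids 21 rose, 3 fell and 14 did not pass, against 25 higher and 5 lower adjusted over the list alone; Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, rose by 1.52 and the clock gene Per1 by 1.66. The list passed camera (adjusted p = 1.63e-15), with adjusted p = 0.131 with an estimated correlation. Of 18 targets of the mineralocorticoid receptor in epithelia 9 rose, also 9 adjusted over the list alone, and none fell (camera adjusted p = 2.27e-08; adjusted p = 0.102 with an estimated correlation), among them Zbtb16 by 2.82 and Orm1 by 1.85. Of 29 alternative activation genes 10 rose and 5 fell, and 11 and 5 adjusted over the list alone (camera adjusted p = 0.00176; adjusted p = 0.160 with an estimated correlation), with Arg1, the arginase of such cells, up by 2.75. The count of 1964 was 1140 without control corticosterone replicate 1, 1050 without replicate 2 and 853 without the variance trend.

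Several groups fell together in control cells. Of 18 genes of cholesterol synthesis 13 fell and none rose, 16 adjusted over the list alone (camera adjusted p = 5.71e-13; adjusted p = 0.0997 with an estimated correlation); Fdft1 fell by 0.53, Mvd fell by 0.53 and Cyp51 fell by 0.50. Of 11 genes of antigen presentation by MHC class II 8 fell, also 8 adjusted over the list alone (camera adjusted p = 2.27e-08; adjusted p = 0.135 with an estimated correlation), among them H2-DMb2, which fell by 1.19, and H2-Ab1, which fell by 0.82. Of 31 cell cycle genes 15 fell, 21 adjusted over the list alone (camera adjusted p = 2.82e-11; adjusted p = 0.160 with an estimated correlation), with Tk1, a thymidine kinase, lower by a log2 change of -1.34. On 8 arrays, which include the array with the high cell cycle list, the median of this list was -1.33 instead of -0.49. B cell markers moved the same way as the MHC class II genes, which B cells also express: 7 of 9 fell, also 7 adjusted over the list alone (camera adjusted p = 7.79e-08; adjusted p = 0.149 with an estimated correlation), and Ms4a1, which encodes CD20, fell by 1.65. Of 13 T and NK cell markers 5 fell, 6 adjusted over the list alone (camera adjusted p = 0.00374; adjusted p = 0.160 with an estimated correlation), and Cd3e fell by 1.49. Of 16 antioxidant genes 7 fell and 2 rose, 8 and 4 adjusted over the list alone (camera adjusted p = 0.0117; adjusted p = 0.160 with an estimated correlation), and Nqo1 fell by 1.10. Of the efferocytosis and complement genes 7 rose and 5 fell, 8 and 6 adjusted over the list alone (camera adjusted p = 0.0117; adjusted p = 0.160 with an estimated correlation). Mast cell and basophil markers did not pass as a list (camera adjusted p = 0.0675), though Fcer1a rose by 1.49.

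**Figure D2:**
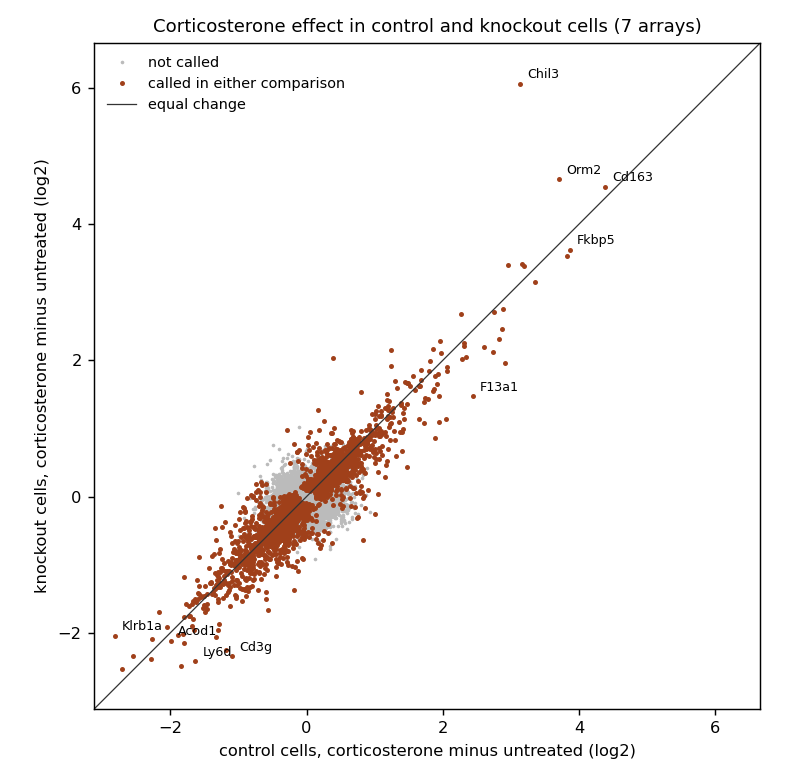
Log2 change with corticosterone in control cells (x axis) against that in knockout cells (y axis) for each gene, from 7 arrays, with a line of equal change. Chil3 lies far above the line, at 3.14 and 6.06, and Fkbp5, at 3.86 and 3.62, near it.

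Knockout cells responded to corticosterone with many of the same genes. On 8 arrays Chil3 rose by 6.06 log2 units (SE 0.16, adjusted p = 0.000721), from 6.25 ± 0.19 to 12.31 ± 0.01 (SD, n = 2). Orm2 rose by 4.66, Cd163 by 4.55, Fkbp5 by 3.62, Nipal1 by 3.40, Cbr2 by 2.46, Ms4a6c by 2.04, Gm11827 by 1.92, Rnase4 by 1.84 and the organic anion transporter gene Slco2b1 by 1.84. Acap1 fell by 2.38, the T cell receptor chain gene Cd3g fell by 2.34, Plac8 fell by 2.15, the T cell adaptor gene Lat fell by 1.76, Ryr1 fell by 1.58, Hivep3 fell by 1.00 and Fn1 fell by 0.79. Other probe sets gave 0.42 for Ms4a6c, 0.07 to 1.45 for Slco2b1, 0.26 to 3.61 for Fkbp5, -0.08 for Ryr1 and -0.73 to -0.03 for Hivep3. limma called 27 genes, 20 higher and 7 lower, of which 19 higher and 3 lower were also called in control cells, and 836 had an unadjusted p under 0.05. Of 10 gene lists that passed camera, 4 held with an estimated correlation: glucocorticoid-induced genes (4 of 38 higher; adjusted p = 0.0175), epithelial receptor targets (0 of 18 called; adjusted p = 0.0378), B cell markers (0 of 9 called; adjusted p = 0.0380) and T and NK cell markers (1 of 13 lower; adjusted p = 0.0378). Adjusted over the list alone, 13 rose and 1 fell, 4 rose, 5 fell and 3 fell in the same order. The count was 0 without either knockout corticosterone array, 1 without either control corticosterone array, 2 without knockout untreated replicate 1, 1 without replicate 2, 2433 without control untreated replicate 1 and 2493 without its replicate 2. It was 1956 with array weights, 43 without the variance trend and 1920 with only the arrays compared.

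The 2493 genes called with 7 arrays were 1046 higher and 1447 lower. Lyve1 rose by 3.52, Sult1a1 by 3.41, Cdo1 by 3.39, Ms4a6b by 3.15 and Ddit4, an inhibitor of mTOR that glucocorticoids induce, by 2.75, while Ipcef1 fell by 2.52, Gimap8 fell by 2.49, Ly6d fell by 2.42, Psrc1 fell by 2.34 and Acod1 fell by 2.11. The 2 other probe sets of Ipcef1 gave -0.25 and -0.04. Of the glucocorticoid-induced genes 20 rose and 3 fell, and 21 and 4 adjusted over the list alone (camera adjusted p = 5.55e-14; adjusted p = 0.117 with an estimated correlation). Of the epithelial receptor targets 9 rose and none fell, also 9 adjusted over the list alone, although the receptor gene is deleted in these cells (camera adjusted p = 7.76e-08; adjusted p = 0.115 with an estimated correlation). Of the alternative activation genes 13 rose and 7 fell, and 14 and 7 adjusted over the list alone (camera adjusted p = 0.000835; adjusted p = 0.144 with an estimated correlation). Of the cholesterol synthesis genes 17 of 18 fell, also 17 adjusted over the list alone (camera adjusted p = 5.55e-14; adjusted p = 0.0891 with an estimated correlation), and of the cell cycle genes 21 of 31, 25 adjusted over the list alone (camera adjusted p = 1.35e-13; adjusted p = 0.144 with an estimated correlation). Of the MHC class II genes 8 of 11 fell, also 8 adjusted over the list alone (camera adjusted p = 3.67e-09; adjusted p = 0.117 with an estimated correlation); H2-Eb1 fell by 1.12. B cell markers again fell beside them, 7 of 9, and 8 adjusted over the list alone (camera adjusted p = 3.67e-09; adjusted p = 0.117 with an estimated correlation), with Ms4a1 down by a log2 change of -1.96. Of the T and NK cell markers 5 fell and 1 rose, and 7 and 1 adjusted over the list alone (camera adjusted p = 0.000867; adjusted p = 0.144 with an estimated correlation); Cd3e fell by 1.69. Antioxidant genes (8 of 16 fell and 4 rose, 9 and 4 adjusted over the list alone), stress and unfolded protein genes (6 of 20 rose and 2 fell, 8 and 3 adjusted over the list alone) and efferocytosis and complement genes (8 of 25 rose and 6 fell, 11 and 7 adjusted over the list alone) passed camera at adjusted p = 0.00857, 0.0363 and 0.0482, with adjusted p = 0.144, 0.193 and 0.193 with an estimated correlation. The efferocytosis and complement list lost its call without knockout untreated replicate 1 (camera adjusted p = 0.0677), without knockout corticosterone replicate 1 (0.0767) and with 5 arrays (0.0733), and the stress and unfolded protein list without knockout untreated replicate 1 (0.0582). The count of 2493 was 1642 without knockout corticosterone replicate 1, 1479 without replicate 2 and 1289 without the variance trend.

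The size of the hormone response differed between genotypes for 3 genes with 7 arrays. Chil3 rose by 3.14 log2 units in control and by 6.06 in knockout cells, an interaction of 2.92 (SE 0.12, adjusted p = 3.4e-05). Before treatment Chil3 was lower in knockout cells, at 6.25 ± 0.19 against 8.34 on control untreated replicate 1, and after it higher, at 12.31 ± 0.01 against 11.48 ± 0.03 (SD, n = 2). F13a1, which encodes coagulation factor XIII A, rose by 2.44 in control and 1.47 in knockout cells (interaction -0.97, SE 0.07, adjusted p = 0.0011). Hp, which encodes haptoglobin, stood at 10.47 ± 0.04 in knockout untreated and 10.44 ± 0.05 in knockout corticosterone cells, against 8.40 on control untreated replicate 1 and 9.23 ± 0.03 in control corticosterone cells (interaction -0.86, SE 0.08, adjusted p = 0.0105). With 8 arrays limma called 0 genes, with 199 at an unadjusted p under 0.05. There the interaction of Chil3 was 2.77 (SE 0.22, adjusted p = 0.423). The count with 7 arrays was 8 without knockout untreated replicate 1, 5 without replicate 2 and 0 without the variance trend. Hp lost its call without control corticosterone replicate 1 (adjusted p = 0.249), its replicate 2 (adjusted p = 0.176) or knockout corticosterone replicate 1 (adjusted p = 0.0887).

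**Figure D3:**
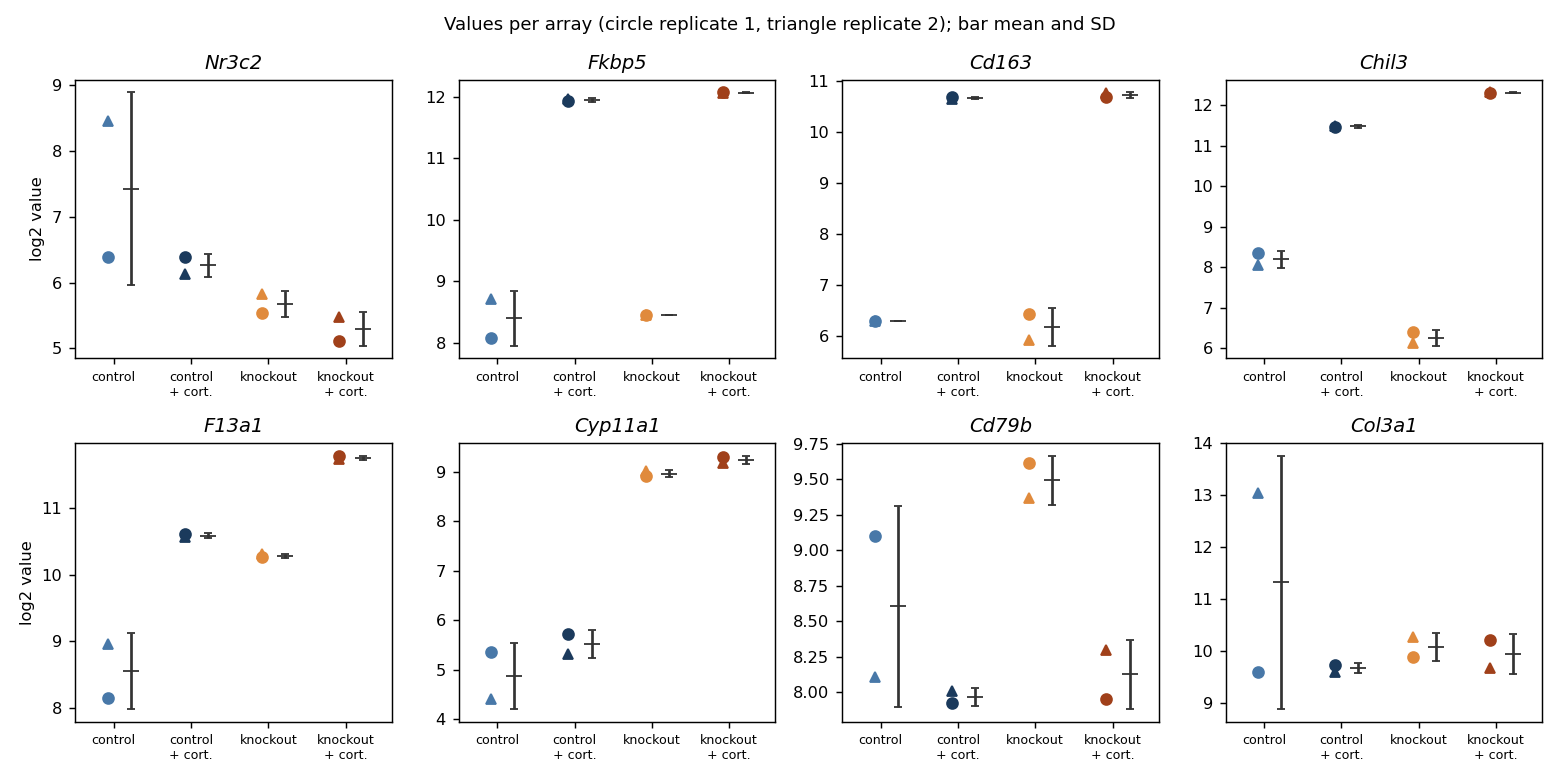
Log2 level of 8 genes on each array by group, with group mean and SD as bars (n = 2). Chil3 is lowest in knockout untreated cells, at 6.25, and highest in knockout corticosterone cells, at 12.31; Cyp11a1 is above 8.8 on each knockout array.

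Akr1cl, Hsd3b1, Aldh1a1 and Cyp11a1 were among the genes with the largest increases in knockout cells without hormone when 7 arrays were used. Akr1cl, an aldo-keto reductase gene, was higher by 4.64 log2 units (SE 0.29, adjusted p = 4.14e-05), Hsd3b1, a hydroxysteroid dehydrogenase gene, by 3.83 (SE 0.22), Aldh1a1, which makes retinoic acid, by 3.81 (SE 0.14) and Cyp11a1, which carries out the first step of steroid synthesis from cholesterol, by 3.61 (SE 0.16). Nrn1 was higher by 3.43, Ephx2, a soluble epoxide hydrolase gene, by 3.34, Bex4 by 3.31, Inha, the inhibin alpha subunit gene, by 3.23, Hs6st2 by 3.23 and Cemip by 3.20. Lower were 2610035D17Rik, by a log2 change of -3.11 (SE 0.41), Chil3 at -2.09 (SE 0.10), Capn11 at -1.56, Zfp874a at -1.52, Rab6b at -1.41, Ctr9 at -1.24, the E-cadherin gene Cdh1 at -1.18, Zfp982 at -1.12, Rsl1 at -1.02 and Npas2 at -0.81. For some of these genes other probe sets gave smaller or opposite values: 0.49 for Akr1cl, -0.0025 to 0.40 for Cyp11a1, -0.40 to 0.57 for Hs6st2, -0.56 to 0.22 for Cemip, -0.33 to 0.34 for Ctr9, -0.16 to 0.33 for Zfp982, 0.03 for Npas2 and 0.11 for 2610035D17Rik. The 3 other probe sets of Rab6b all went the same way, at -1.41 to -0.22. The list of 12 steroid receptors and prereceptor enzymes had 1 higher, 2 higher and 1 lower adjusted over the list alone, and did not pass (camera adjusted p = 0.353; adjusted p = 0.515 with an estimated correlation). With 8 arrays limma called 0 genes in this comparison, with 807 at an unadjusted p under 0.05. The gene with the smallest p, Ephx2, was at 3.54 with adjusted p = 0.0668. Of the lists 10 passed camera with 8 arrays and none with an estimated correlation or with fry.

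With 7 arrays 362 genes were called, 261 higher and 101 lower in knockout cells; with arrays centred on their medians the split was 235 higher and 156 lower. The list of 11 MHC class II genes had 6 higher, 7 adjusted over the list alone, and none lower (camera adjusted p = 9e-10; adjusted p = 0.202 with an estimated correlation); H2-Eb1 was higher by 0.88 and Cd74, the invariant chain gene, by 0.58. B cell markers, which share expression of these genes, had 1 of 9 higher, 3 adjusted over the list alone (camera adjusted p = 0.0091; adjusted p = 0.409 with an estimated correlation), with Cd79a at 0.51. Of 32 inflammatory genes 8 were higher, also 8 adjusted over the list alone (camera adjusted p = 2.97e-05; adjusted p = 0.202 with an estimated correlation), among them the formyl peptide receptor gene Fpr2 by 1.92 and Tlr2 by 0.75. Of 31 cell cycle genes 7 were higher, 17 adjusted over the list alone (camera adjusted p = 2e-12; adjusted p = 0.240 with an estimated correlation), with Tk1 at 0.93. Of 25 efferocytosis and complement genes 7 were higher and 2 lower, 10 and 3 adjusted over the list alone (camera adjusted p = 0.016; adjusted p = 0.240 with an estimated correlation); the median of this list was 0.018 and turned to -0.0082 with median centring. Cfb, which encodes complement factor B, was higher by 1.35 and C1qa by 0.44. Of 29 interferon-stimulated genes 1 was lower, 2 adjusted over the list alone (camera adjusted p = 0.0157; adjusted p = 0.240 with an estimated correlation): Bst2, at -0.41. With 8 arrays this list passed in the opposite direction, with a median of 0.31 and none called in either count (camera adjusted p = 0.017; adjusted p = 0.621 with an estimated correlation). Beyond these lists F13a1 was higher by 2.13, the fractalkine receptor gene Cx3cr1 by 2.16 and Pdk4, a kinase that restrains glucose oxidation, by 3.02. The lists of glucocorticoid-induced genes (7 higher and 1 lower, 13 and 6 adjusted over the list alone), immediate early genes (2 higher, 4 higher and 2 lower adjusted over the list alone) and cholesterol synthesis genes (none in either count) passed camera at adjusted p = 0.0359, 0.023 and 0.0179, with adjusted p = 0.515, 0.515 and 0.240 with an estimated correlation. The glucocorticoid-induced list lost its call without control corticosterone replicate 1 or 2 (camera adjusted p = 0.0637 and 0.0639), without knockout untreated replicate 2 (0.0503) and with 5 arrays (0.0574). Without knockout untreated replicate 2 the calls of cholesterol synthesis (0.0503) and immediate early genes (0.138, and 0.0794 with 5 arrays) were lost, and without replicate 1 that of B cell markers (0.0503). The calls of Rsl1 and Cd79a were lost without either control corticosterone array (adjusted p = 0.0869 and 0.0863 for Rsl1, 0.0764 and 0.0767 for Cd79a). The count of 362 was 183 without either control corticosterone array, 927 without knockout untreated replicate 1, 147 with only the arrays compared and 65 without the variance trend.

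**Figure D4:**
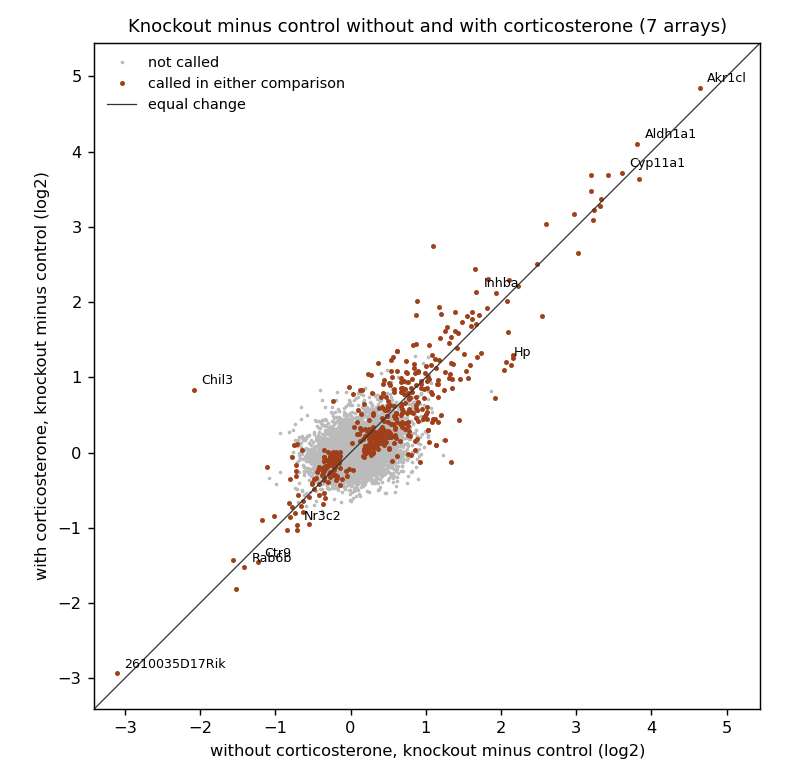
Log2 difference between knockout and control cells without corticosterone (x axis) against that with corticosterone (y axis) for each gene, from 7 arrays, with a line of equal difference. Akr1cl, at 4.64 and 4.85, and Aldh1a1, at 3.81 and 4.10, lie far to the upper right.

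With corticosterone present much the same genes differed between genotypes. The labels do not say whether the cultures without and with hormone came from separate mice. Agreement between these 2 comparisons is therefore not a separate repeat of the genotype difference. With 7 arrays Akr1cl was higher in knockout cells by 4.85 log2 units (SE 0.23), Aldh1a1 by 4.10 (SE 0.12, adjusted p = 3.86e-07), Cyp11a1 by 3.72 (SE 0.13), Nrn1 by 3.69, Ankrd1 by 3.69, Hsd3b1 by 3.64, Cemip by 3.47, Ephx2 by 3.38, Bex4 by 3.28 and Inha by 3.23. Lower were 2610035D17Rik at -2.94, Zfp874a at -1.81, Rab6b at -1.52, Ctr9 at -1.46, Capn11 at -1.43, Misp3 at -1.03, Cyp4f18 at -1.03, Nr3c2 at -0.97, the chemokine gene Ccl8 at -0.95 and Cdh1 at -0.90. Other probe sets gave smaller or opposite values for Akr1cl (0.39), Cyp11a1 (-0.15 to 0.15), Cemip (-0.18 to -0.06), 2610035D17Rik (-0.44), Ctr9 (-0.25 to -0.06) and Cyp4f18 (-0.04). The call covered 296 genes, 235 higher and 61 lower, and 151 higher and 34 lower genes were shared with the comparison without hormone, where independent lists would share 3.37 and 0.339. Cell cycle genes were higher for 12 of 31, 21 adjusted over the list alone (camera adjusted p = 8.78e-20; adjusted p = 0.187 with an estimated correlation), with Bub1 at 1.26 and Prc1 at 0.73. MHC class II genes were higher for 5 of 11, 6 adjusted over the list alone (camera adjusted p = 1.67e-10; adjusted p = 0.122 with an estimated correlation), H2-Ab1 by 0.63, while no B cell marker was called and their list did not pass (camera adjusted p = 0.5). Of the interferon-stimulated genes 3 were lower, also 3 adjusted over the list alone (camera adjusted p = 1.88e-05; adjusted p = 0.122 with an estimated correlation): Bst2 at -0.56, Oas3 at -0.33 and Rsad2 at -0.28. Of 18 cholesterol synthesis genes none passed, in either count, though the median was -0.075 (camera adjusted p = 1.04e-05; adjusted p = 0.122 with an estimated correlation). Matrix genes were higher for 5 of 24, with 9 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.00138; adjusted p = 0.341 with an estimated correlation), Lox, the lysyl oxidase gene, by 0.86 and Fn1 by 0.43. Mesothelial and fibroblast markers moved with them, with 1 of 14 higher, also 1 adjusted over the list alone, and all 14 positive (camera adjusted p = 8.47e-05; adjusted p = 0.354 with an estimated correlation); Sparc was higher by 0.49. The mean of this list was 7.52 and 7.15 on knockout corticosterone replicate 1 and 2, against 7.04 and 7.02 on the control corticosterone arrays, and its call was lost without knockout corticosterone replicate 1 (camera adjusted p = 0.103) and with 5 arrays (0.0504). Inflammatory genes had 2 higher, 7 adjusted over the list alone (camera adjusted p = 0.00562; adjusted p = 0.187 with an estimated correlation). Of the alternative activation genes 5 were higher and 2 lower, 8 and 4 adjusted over the list alone (camera adjusted p = 0.0404; adjusted p = 0.324 with an estimated correlation), and of 10 markers of resident peritoneal macrophages 1 was higher, also 1 adjusted over the list alone (camera adjusted p = 0.00993; adjusted p = 0.232 with an estimated correlation). The alternative activation list lost its call without control corticosterone replicate 1 or 2 (camera adjusted p = 0.0507 and 0.0709), and both lists did without knockout corticosterone replicate 2 (0.0770 and 0.0800).

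With all 8 arrays limma called 0 genes in the comparison with corticosterone, with 229 at an unadjusted p under 0.05, although the fold changes are the same 4 arrays' values. The smallest adjusted p was 0.0689. Of the lists 7 passed camera with 8 arrays and none with an estimated correlation or with fry. From only those 4 arrays limma called 490 genes, 372 higher and 118 lower, and with array weights 264. Without control untreated replicate 1 the count of 8 arrays was 274, and without replicate 2 it was 296. The count of 7 arrays was 115 without control corticosterone replicate 1, 94 without replicate 2, 475 and 476 without knockout untreated replicate 1 and 2, and 132 and 197 without knockout corticosterone replicate 1 and 2. It was 194 with 5 arrays and 86 without the variance trend. Of the genes named with 7 arrays, Misp3 lost its call without any 1 of the 4 arrays compared (adjusted p up to 0.220). Without control corticosterone replicate 2 the calls of 2610035D17Rik (adjusted p = 0.0671), Rab6b (0.0637), Prc1 (0.0870), Oas3 (0.146) and Capn11 (0.105) were lost, and without knockout corticosterone replicate 1 those of Capn11 (0.0505) and Oas3 (0.118). Cyp4f18, Ccl8, Bub1, Lox, Sparc and Rsad2 lost theirs without control corticosterone replicate 1 (0.0694, 0.321, 0.101, 0.323, 0.180 and 0.204) or replicate 2 (0.0719, 0.328, 0.137, 0.290, 0.250 and 0.379), as did Ccl8, Bub1, Lox and Sparc without knockout corticosterone replicate 1 (0.281, 0.0529, 0.224 and 0.0960) and Rsad2 without its replicate 2 (0.213).

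Averaged over culture conditions, 7 genes passed on 8 arrays, all higher in knockout cells: Akr1cl by 4.85 log2 units (SE 0.23, adjusted p = 0.00966), Cyp11a1 by 3.90 (SE 0.24, adjusted p = 0.0170), Aldh1a1 by 3.74 (SE 0.22), Hsd3b1 by 3.65 (SE 0.18), Ephx2 by 3.46 (SE 0.16), Greb1, an oestrogen-responsive gene, by 3.23 (SE 0.23) and Bex4 by 3.23 (SE 0.19). Other probe sets gave 0.43 for Akr1cl, -0.15 to 0.24 for Cyp11a1 and 0.06 to 0.72 for the 3 others of Greb1. At an unadjusted p under 0.05 there were 599 genes. Of 8 lists that passed camera none held with an estimated correlation; the MHC class II genes had none called, 6 of 11 higher adjusted over the list alone, adjusted p = 1.04e-05, and adjusted p = 0.592 with an estimated correlation. The count was 0 without any 1 of the 6 arrays outside the control untreated group, 10786 without control untreated replicate 1 and 777 without replicate 2. Those 777 were 537 higher and 240 lower, or 467 and 410 with median centring, and Ctr9 at -1.35, Cdh1 at -1.04, Misp3 at -0.94 and Nr3c2 at -0.84 (SE 0.14, adjusted p = 0.00929) were among the lower. Nr3c2 lost this call without control corticosterone replicate 1 (adjusted p = 0.0729) and without the variance trend (adjusted p = 0.0817). The 777 became 338 and 356 without control corticosterone replicate 1 and 2, 1486 without knockout untreated replicate 1, 445 without knockout corticosterone replicate 1 and 242 without the variance trend.

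The average corticosterone effect gave 150 genes on 8 arrays, 84 higher and 66 lower. Chil3 rose by 4.67 log2 units, Cd163 by 4.46, Orm2 by 4.27, Sult1a1 by 3.62, Lyve1 by 3.28, Arg1 by 3.07, Cdo1 by 2.86 and the bile acid transporter gene Slc10a6 by 2.81. Klrb1a fell by 2.37, Psrc1 fell by 2.26, Gimap8, Plac8, Ikzf3, Fgr, Pald1 and 5430437J10Rik also fell, and Snn fell by 1.72 on its brightest probe set, while its other probe set gave 0.10. Glucocorticoid-induced genes had 8 higher and none lower, 15 higher and 1 lower adjusted over the list alone, and this list passed camera both ways (adjusted p = 9.1e-11; adjusted p = 0.0339 with an estimated correlation). The count of 150 was 11014 without control untreated replicate 1 and 3558 without replicate 2, 13 without either control corticosterone array, 14 and 15 without knockout untreated replicate 1 and 2, and 12 without either knockout corticosterone array. With 7 arrays 1543 rose and 2015 fell.

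Across 18193 genes, the corticosterone response correlated between genotypes with Pearson's r of 0.747 and Spearman's rho of 0.489 with 7 arrays, against a chance value of -0.001 (covariance 0.0650). With 8 arrays r was 0.352 and rho 0.293. Of 2925 genes called in either genotype with 7 arrays, 2810 had the same sign. Called in both were 674 higher and 857 lower genes, where independent lists would share 50.7 and 86.1, and 1 gene went opposite ways. The genotype effect correlated between culture conditions with r of 0.599 and rho of 0.311 with 7 arrays, and with r of -0.0367 and rho of -0.0158 with 8. Both averages use every array, and with the control untreated group at 1 array their errors are correlated: with 7 arrays r was 0.0271 and rho 0.0852, where no effect gives r of 0.2, and the covariance was 0.00155 against 0.00177. With 8 arrays r was 0.623, which rests on control untreated replicate 2. That array enters both averages with the same sign, and without it r was 0.0271. Of the genes higher in knockout cells 139 also rose with corticosterone and 131 fell, where independent lists would share 45.5 and 59.5; of the lower ones 103 also fell and 41 rose, against 26.6 and 20.4. Part of the excess may come from the shared arrays, and the control untreated group has too few to split.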

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

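The tests of broken RNA and of single Y-linked probe sets were chosen only after the result they bear on was seen; the other tests were written before theirs. For 31 measures, made of array quality values, the means of the gene lists and sex-linked genes, the 8 arrays were searched for a value far from the rest, and 14 had one. Chance gives about 1 in 20, and the measures share the same arrays. In each of the 14 it was control untreated replicate 2: its median correlation with the other arrays (0.919), its 3′ minus 5′ differences for Actb (2.18) and Gapdh (1.84), its means for the lists of inflammatory genes (6.54), interferon-stimulated genes (7.82), circadian clock (7.85), efferocytosis and complement (10.2), stress and unfolded protein genes (9.78), antioxidant genes (10.995), macrophage identity (11.3), resident peritoneal macrophages (7.25), mesothelial and fibroblast markers (8.95) and erythroid markers (5.33), and its level of the Y-linked gene Eif2s3y (10.06, against 4.31 to 5.60 on the others).

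On this array 1601 genes lay over 2 log2 units above the other control untreated array and 265 that far below. A swap with a corticosterone array is argued against by its position on an axis of 50 hormone genes, -0.0706, where untreated arrays define 0 and hormone arrays 1. The Actb 3′ minus 5′ difference exceeded the highest of the other 7 arrays by 1.56, against a range of 0.206 among them, so broken or truncated RNA may be part of it and cannot be told apart from a different sample, as the test was chosen after the value; as the cause of the raised transcripts it is argued against by Eif2s3y, 4.46 above the highest of the others, since broken RNA adds no transcript. Cells of another type remain a candidate source: mesothelial and fibroblast markers had a median deviation of 1.76 from the replicate, 9 of 14 by over 1 log2 unit, against a 99th percentile of 0.484 for random lists, with Col3a1 at 13.04 and Col1a2 at 12.53. The adherence step in the labels would remove only cells that do not adhere, and the design gives no biological explanation for a single array, so none was tested.

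Cyp11a1, Hsd3b1, Inha and Greb1 were higher on each of the 4 knockout arrays than on each control array on their brightest probe sets. For Inha the closest were 6.73 on knockout corticosterone replicate 2 and 6.70 on control untreated replicate 2. Star (0.08), Cyp17a1 (-0.03), Hsd17b1 (0.07) and Hsd17b7 (-0.07) did not pass in the comparison with corticosterone and 7 arrays. Adrenal cells are argued against by 4 measured adrenal markers with a median difference of 0.0389 (SD 0.227) in the comparison with corticosterone; testis and oocyte markers had medians of -2.76e-05 and -0.0212. For ovarian cells, 21 measured markers listed before this test, among them Inha and Greb1 of the pattern itself, had a median of 0.0786. That was below the bound of 0.5 set beforehand and inside the 99th percentile of random lists, 0.0923. That bound does not decide, because some markers rose while the rest lay near 0, with an SD of 1.10. Over 1 log2 unit lay 5 of 21, Inha, Inhba, Greb1, Fst and Sfrp4. Foxl2 (0.93) and Gata4 (0.80) lay just under that limit. Amhr2 (0.03) and Fshr (0.07) lay near 0, and the lowest marker was Ptgfr at -0.23. Scarb1, Hsd17b7 and Ptgis are expressed by the control macrophages as well. The rise of Inha and Greb1 is the pattern itself and no separate evidence. Induction in macrophages by the deletion, which the design names, also stays open. A share of 0.357 of 14 ovarian markers outside steroid synthesis, Inha and Greb1 included, lay over 1 log2 unit, which could come with either. Of these, Fst and Inha were also high on control untreated replicate 2. Fst was 10.28 there, 7.57 to 7.79 on the knockout arrays and 5.72 to 6.11 on the other control arrays. Inha was 6.70 there and 3.19 to 3.96 on the other control arrays. Inhba (6.09), Greb1 (3.31) and Sfrp4 (5.21) lay well below the knockout arrays there. Whether such signal adds to the share was not tested.

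Xist, the transcript of the inactive X chromosome, lay between 12.05 and 12.27 on all 8 arrays on its brightest probe set although the labels say male; its 2 other probe sets read 9.96 and 8.02 on control untreated replicate 2, against 10.85 to 11.12 and 9.93 to 10.21 on the others. Of 4 Y-linked genes 3 were measured, and their median lay at most at the 20.9th percentile of all genes on any array. That value met the bounds set beforehand, for female cells in the pools and against male and female cells mixed. The median decides neither, because the probe sets standing for Kdm5d and Uty did not respond on control untreated replicate 2 while others of the same genes did. A further Kdm5d probe set read 6.84 on control untreated replicate 2 and 2.13 to 3.10 on the other 7 arrays. For a further Uty probe set the values were 6.21 and 2.17 to 2.65. On the other 7 arrays these probe sets thus stayed low while Xist lay at 12.05 or above. That argues against male cells alone on those 7 arrays, and a small share of male cells is not excluded. On control untreated replicate 2, 4 of 9 Y-linked probe sets lay over 2 log2 units above the other 7 arrays. Male cells on the array that stands apart may therefore be part of it, which stays open as the test was chosen after the values. Sex is not a group of the design, so no biological explanation was tested.

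The corticosterone response differed between genotypes in the interaction for Chil3 (2.92), F13a1 (-0.97) and Hp (-0.86) with 7 arrays. Gene lists differed in the interaction by camera at the preset correlation, none of them with an estimated one (adjusted p = 0.667 for each with 8 arrays, and 0.666 to 0.694 with 7). With 8 arrays the adjusted p was 0.0180 for inflammatory genes, 0.00193 for interferon-stimulated genes, 0.0348 for MHC class II, 0.000272 for cell cycle, 0.0444 for cholesterol synthesis, 0.0355 for immediate early genes, 0.00413 for efferocytosis and complement, 0.0396 for antioxidant genes, 0.0444 for B cell markers and 6.02e-05 for mesothelial and fibroblast markers. With 7 arrays it was 0.00665 for inflammatory genes, 0.00665 for MHC class II, 0.0468 for immediate early genes, 0.0368 for efferocytosis and complement, 0.0224 for B cell markers and 0.0224 for mesothelial and fibroblast markers. With 7 arrays each of these lists but the inflammatory genes lost its call without control corticosterone replicate 2 (0.0969, 0.208, 0.138, 0.109 and 0.0969 in the same order). Immediate early genes and efferocytosis and complement also lost it without knockout untreated replicate 2 (0.317 and 0.0648) or knockout corticosterone replicate 2 (0.361 and 0.164), and B cell markers and mesothelial and fibroblast markers without knockout untreated replicate 1 (0.139 for both) or knockout corticosterone replicate 1 (0.0737 and 0.706). With 8 arrays interferon-stimulated, cell cycle, cholesterol synthesis and antioxidant genes lost theirs without control untreated replicate 2 (0.633, 0.884, 0.690 and 0.826). Each of the other 7 arrays, left out singly, ended at least 1 of the calls of MHC class II, cholesterol synthesis, immediate early genes, antioxidant genes and B cell markers (0.0516 to 0.157).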

How the results depend on the processing

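The fits of 7 and 5 arrays and every alternative applied to them were chosen after seeing the data; the other alternatives were chosen before. With 8 arrays, calls changed as follows, and unless stated the cause was not tested. With only the arrays compared, which leaves out other groups' spread, the counts were 490 with 372 higher and 118 lower for genotype with corticosterone, 0 for corticosterone in control cells and 1920 in knockout cells; array weights gave 264, 7 and 1956. The mean of probe sets gave 3 and 4 genes for genotype without and with corticosterone, and no variance trend gave 43 for corticosterone in knockout cells. Leaving out 1 array gave 0 to 11715 for genotype without, 0 to 296 with, 0 to 11678 for corticosterone in control and 0 to 2493 in knockout cells, 0 to 10675 for the interaction, 0 to 10786 for average genotype and 12 to 11014 for average corticosterone. Correlations ranged from 0.20016 to 0.747 for the hormone response between genotypes, -0.155 to 0.599 for the genotype effect between conditions and 0.0271 to 0.879 between both effects.

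Gene lists that passed with 8 arrays numbered 10, 7, 11, 10, 10, 8 and 12 in the order genotype without, with, corticosterone in control, in knockout, interaction, average genotype, average corticosterone; with an estimated correlation 0, 0, 0, 4, 0, 0 and 1, with fry 0, 0, 6, 5, 0, 0 and 8. Without the dim genes 5 passed for genotype without, 6 for the interaction and 4 for average genotype. Leaving out 1 array gave 9 to 14, 5 to 10, 8 to 11, 9 to 11, 5 to 11, 7 to 14 and 7 to 13. The 1 reversal was the list of genes that are interferon stimulated in genotype without corticosterone, higher with 8 arrays and lower without control untreated replicate 2 (adjusted p = 0.0157); leaving out 1 array gave it an adjusted p of 0.000487 to 0.0343.

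With 7 arrays no variance trend gave 65, 86, 853, 1289, 0, 242 and 2063 genes in the same order. A minimum of 1.5-fold, which tests the same genes and removes small changes, gave 180, 178, 682, 720, 3, 258 and 702. Only the arrays compared gave 147 for genotype without and 490 with corticosterone, and 5 arrays gave 194 with. Leaving out 1 array gave 183 to 927, 94 to 476, 1050 to 2567, 1479 to 2992, 2 to 8, 338 to 1486 and 2524 to 4220. The hormone correlation was 0.880 without dim genes, 0.703 with 5 arrays and 0.685 to 0.724 with 1 array left out; the genotype correlation 0.763, 0.508 and 0.531 to 0.570; between both effects it was -0.0692 to 0.0822. Lists passing with an estimated correlation were 0 in all 7 contrasts; fry gave 5 for genotype without, 17 and 18 for corticosterone in control and knockout cells, 0 for the interaction and 19 for average corticosterone. For the interaction 5 arrays gave 1 list and leaving out 1 array 1 to 6.

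The values gave no clear sign that the replicate numbers pair the samples: correlations of replicate differences between groups ran from -0.292 to 0.397. Both ends of this range involve the control untreated group, so they also carry the signal of the array that stands apart. A shared animal or day behind a replicate number is not excluded. With the number as a block, counts were 6 and 1 for corticosterone in control and knockout cells, 3 for average genotype and 49 for average corticosterone with 8 arrays, and 186 for genotype without, 468 for average genotype and 3 lists in the interaction with 7; the block uses a degree of freedom. With the block the other counts stayed within 1.5 times, and Nr3c2 in genotype with corticosterone, 7 arrays, had adjusted p = 0.0591. For single genes named with 7 arrays, 2910 results kept their call with 1 array left out and 230 lost it; of those not called, 273 stayed so and 7 gained a call. For genes named with 8 arrays, 215 results kept their call with 1 array left out and 473 lost it. Of those not called, 501 stayed so and 75 gained a call. The deposited values hold no detection call, so how far signal over background limits single genes was not tested.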

Other observations

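The test of chromosome neighbours was thought of after the names of lower genes were seen, though written before its value; the tests around Lyz2 and of other splits were written before their results, except the count of balanced splits, and results from 7 arrays were chosen after seeing the data. Members of the clock and lipid handling lists changed in both directions with corticosterone with 7 arrays, and neither list passed camera. The clock genes Per1 and Nfil3 rose by 1.66 and 1.06 log2 units in control cells and by 1.62 and 0.89 in knockout cells, while Per3 changed by -1.22 and -1.16 and Bhlhe40, a repressor of clock genes, by -0.72 and -0.74. Of 17 clock genes 3 rose and 6 fell in each genotype, 4 and 8 adjusted over the list alone in control and 4 and 7 in knockout cells, and the list did not pass camera (adjusted p = 0.206 and 0.393). Of 22 genes of lipid handling 4 rose and 8 fell in control cells, 6 and 9 adjusted over the list alone, and 5 and 9 in knockout cells, 8 and 11 adjusted over the list alone (camera adjusted p = 0.325 and 0.520): Fasn, the fatty acid synthase gene, changed by -0.63 and -0.68 and Scd2, a desaturase gene, by -0.63 and -0.51, while Apoe rose by 0.46 and 0.35 and Fabp4 by 0.26 and 0.26. Among the stress and unfolded protein genes, Asns and Phgdh, which make asparagine and serine, rose by 0.44 and 0.48 in control and by 0.50 and 0.36 in knockout cells, and Slc7a11, the cystine transporter gene, changed by -0.89 and -0.80.

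Markers of other leukocytes moved in both directions with corticosterone. Fcer1a, the IgE receptor gene of mast cells and basophils, rose by 1.49 in control and 1.67 in knockout cells and the mast cell protease gene Cpa3 by 0.70 and 0.78, whereas Gata2 changed by -0.82 and -1.08. Of 11 such markers 4 rose and 1 fell in control cells, also 4 and 1 adjusted over the list alone, and 3 rose and 1 fell in knockout cells, 5 and 1 adjusted over the list alone (camera adjusted p = 0.0675 and 0.0662). Of 11 dendritic cell markers 3 fell in control cells, with 3 lower and 1 higher adjusted over the list alone, and 4 fell and 1 rose in knockout cells, also 4 and 1 adjusted over the list alone (camera adjusted p = 0.0609 and 0.0891), with Ccr7 at -1.24 and -0.91. In control cells the call of Cpa3 was lost without control corticosterone replicate 1 or 2 (adjusted p = 0.0690 and 0.0900), as was that of Ccr7 (adjusted p = 0.0731 and 0.0692). In knockout cells Ccr7 lost its call without knockout untreated replicate 1 (adjusted p = 0.0523) or knockout corticosterone replicate 2 (adjusted p = 0.115). Of 11 neutrophil markers 2 rose and 1 fell in control cells, also 2 and 1 adjusted over the list alone, and 2 rose and 2 fell in knockout cells, 2 and 3 adjusted over the list alone (camera adjusted p = 0.348 and 0.793); in knockout cells their median was -0.026 while the mean, 0.123, and the test were positive. Among them Lcn2, which macrophages also express, rose by 2.31 and 2.25. Of 6 eosinophil markers 1 fell in control and 2 fell in knockout cells, also 1 and 2 adjusted over the list alone (camera adjusted p = 0.0511 and 0.261).

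A first hypothesis was that genes near Lyz2, carried along with a Cre allele there, would be called between genotypes more often. Of 200 tested genes flanking Lyz2, 3% were called in the average genotype effect with 7 arrays, against 4.31% elsewhere (Fisher's exact test, one-sided, p = 0.865). That shows no excess in this window of 100 tested genes on each side. A shorter segment with few affected genes would be diluted in it, so the test does not decide the hypothesis. The Cre driver is not given in the sources used here. A second hypothesis is that chromosome segments of another strain may lie behind some of the 240 lower genes. Of these, 9 were followed by another lower gene as the next tested neighbour in assembly GRCm38.p6, against a median of 3 and a 99th percentile of 8 for 10000 random choices, a thin margin; several of the pairs, such as Csf2rb2 and Csf2rb or Zfp991 and Zfp982, are related genes whose probe sets may share sequence, while Misp3 and Il27ra or Tmem236 and Mrc1 are not.

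Other splits of the arrays into 2 sets of 4 (or 3 and 4) were fitted in a model with both factors and no interaction, which gives other counts than the model with 4 groups; the split equal to the other factor was left out. For the average genotype effect the real split gave 8 genes with 8 arrays and 714 with 7, and for the average corticosterone effect 224 and 3675. In each of the 4 tests 1 of 34 splits, the real one, gave as many, and the highest of the others gave 0. Of the 34, 18 were balanced, with as many arrays of each level of the other factor as in the real split. The rest have a larger error by design, so the bound set beforehand over all 34 was wrong, and 18 are too few for a share under 0.05; the other splits also carry the real effect in their residual spread.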
